A study of Mus musculus with 18 samples.

How the data were processed

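RNA from the site of mandibular first molar extraction in mice was sequenced in 18 libraries, 3 biological replicates for each of 2 arms (control and periodontitis) at 0 d, 3 d and 7 d. Per the labels' protocols, total RNA was purified with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina. The deposited table holds raw counts of reads per gene for every library, whole numbers that are not normalized, together with gene symbols, biotypes and coordinates. Per the submitters' processing notes, HISAT2, SAMtools and StringTie were used; their versions, the program that made the counts, its strand setting and the annotation release are not given in the sources used here. The same notes list the mouse build mm9. The coordinates in the table were checked against the gene annotation of build GRCm38 (GENCODE M21): 99.9% of the 54532 gene identifiers occur there and 98.3% of these have the same chromosome, start and end, so coordinates are given as GRCm38. Every row of the table names a gene, and each of the 18 count columns was matched to 1 sample by its title.

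Samples were grouped by arm and day from their titles. Totals per library lay between 14139830 and 17763605 counts, the 10 most abundant genes took 11.0% to 21.1%, mitochondrially encoded genes 1.59% to 4.14% and ribosomal RNA genes 0.108% to 0.817% of counts. At this depth a gene at 1 CPM has few counts, so folds of genes near that level are imprecise. The counts of no pair of libraries in a group agreed within sampling noise (lowest chi-square per gene 11.1). Xist had at most 6 counts in a library and 4 genes of the Y chromosome at least 216, so all 18 libraries came from male mice. The labels state no batch, date or litter.

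Genes were kept by edgeR's filterByExpr on the groups, which left 18697. They were scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with glmQLFit and glmQLFTest, with 1 mean per group and the spread shared over all 18 libraries. Contrasts gave periodontitis against control on each day and over the mean of the days, the 3 changes between days in each arm, and the 2 differences of these changes between arms (interactions). P-values were adjusted by Benjamini-Hochberg within each of the 12 comparisons and called under 0.05; SEs of log2 fold changes were derived from the F statistics. Libraries were not paired, since replicate numbers only name samples. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2.

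Before the data were examined, the design, the alternatives, 27 gene lists and a rule for naming genes were fixed. The rule took, among called protein-coding genes with a mean of at least 1 CPM in a group and groups that do not overlap, the 8 largest rises and 8 largest falls between arms on a day (5 and 5 for the mean of days, the changes with time and, without the condition on overlap, the interactions), plus for each list the called member with the smallest p, up to 3 in lists called between arms on a day and 2 in other comparisons, and always Runx2, Sp7, Bglap, Col1a1, Acp5, Ctsk, Il1b, Il6 and Tnf. Where fewer than 5 genes passed, the 5 with the smallest p were named. The rule names more genes than are printed; those printed were selected from them for length after their values were seen, and Nat10, Hlf and the genes of lists written later were also named after their values were seen. Some gene results are not reported here. The lists were tested with camera (limma 3.58.1) on voom values with the preset correlation of 0.01, two-sided and adjusted over the 26 lists with at least 5 measured members, and again with an estimated correlation and with fry; the salivary gland list had 4 measured members and was not tested. Correlations of arm differences with control time changes were tested by exact permutation of libraries. The pipeline was tested on simulated data: with 200 genes above 5 CPM changed in the comparison at 0 d, 77.6% of those changed 2-fold and 90.9% of those changed 4-fold were called, and at 7 d 64.2% and 93.9%.

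Other settings fixed at the same time were RLE size factors, library totals, no low-count filter, a filter of at least 1 CPM in 9 libraries, removal of the skeletal muscle, erythroid, salivary gland and ameloblast and odontoblast lists, the muscle list as a covariate, a replicate block, DESeq2 1.42.0, a fit of the compared groups alone, and leaving out each library in turn. After the data had been seen, 4 were added: leaving out the 5 libraries whose autonomic ganglion neuron list had a mean log2 CPM above 2, that list as a covariate, both neuron and muscle lists as covariates, and removal of 1165 neuron-associated genes, those higher in the 3 neuron-rich libraries of 3 d. Lists of autonomic and sensory ganglion neurons, marrow precursors, activated neutrophils, ribosome biogenesis and a second dental list were also written after the data had been seen. Haemoglobin, osteocalcin, serum amyloid and eosinophil ribonuclease genes have near-identical copies between which the counting could split reads, and genes that overlap another on the opposite strand are uncertain because the strand setting is unknown. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 and with the R package data.table, version 1.17.8.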

Results

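RNA-seq was used to measure gene expression in the jaws of mice from which the mandibular first molar had been extracted, in a periodontitis arm and a control arm. Periodontitis is an inflammatory disease of the tissues that hold the tooth. The extraction socket is the cavity in the bone that fills with clot, wound tissue and new bone once the tooth is gone. Samples were taken at 0 d, 3 d and 7 d, with 3 biological replicates in each of the 6 groups, which gave 18 libraries. The labels name the first molar as the tissue while the title of the study names the socket, and they do not say which parts of the jaw were collected. Libraries held between 14139830 and 17763605 counts and between 23540 and 25699 genes with at least 1 count. Col1a1, which encodes a chain of the type I collagen of bone and ligament, took 2.96% to 7.94% of the counts of a library.

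Comparisons between arms on each day address which genes differ in the socket with periodontitis, and comparisons between days how the socket changes with time in each arm. Gene values are log2 fold changes ± SE with 3 libraries per group. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 18697 genes. CPM, which are counts scaled to the TMM-adjusted total of a library, are means ± SD of 3 libraries. Gene lists were fixed before the data were examined and tested with camera at its preset correlation of 0.01. Every list called in this way lost its call when the correlation between its genes was estimated, and that p stands beside the first.

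Several libraries held transcripts of cell types that the labels do not name. Genes of autonomic ganglion neurons, a list of 18 assembled after the data were examined, were abundant in 5 libraries. These were control 3 d replicate 2, periodontitis 0 d replicates 1 and 3, and periodontitis 3 d replicates 1 and 2. Vip, a neuropeptide gene of parasympathetic neurons, lay between 213 and 753 CPM in those libraries and at most at 20.6 CPM in the other 13. Of 8 measured genes of sensory neurons, Avil (22.2 to 75.1 against at most 7.28 CPM), Nefh (8.40 to 23.0 against at most 3.05 CPM) and Tac1 (at most 12.6 against at most 2.18 CPM, without overlap) also set these libraries apart. The others overlapped, such as Calca (0.454 to 4.36 against 0.195 to 4.70 CPM). Skeletal muscle genes had their highest mean log2 CPM in periodontitis 0 d replicates 2 and 3 (4.76 and 6.43), 3 d replicate 3 (4.11) and 7 d replicate 1 (3.14). The other 14 libraries reached at most 2.53. The 4 measured salivary gland genes had a mean log2 CPM of 3.48 in control 7 d replicate 3 and 3.17 in control 3 d replicate 2, against at most 0.94 elsewhere. Dspp, the main non-collagen matrix gene of dentine, was at 589 CPM in control 0 d replicate 1 and at 9.14 and 8.18 CPM in the other control libraries of 0 d.

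**Figure D1:**
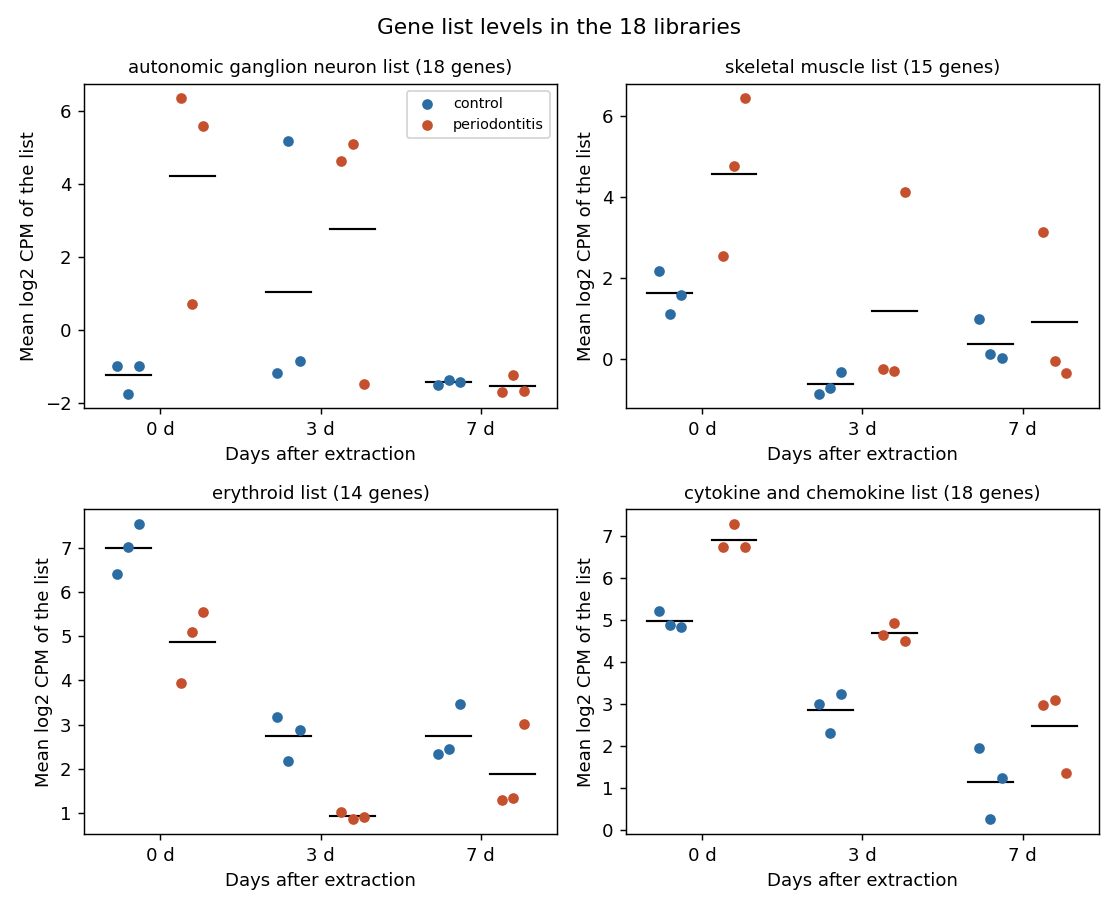
Mean log2 CPM of the autonomic ganglion neuron, skeletal muscle, erythroid and cytokine and chemokine lists (vertical axes) against days after extraction (horizontal axes). Each point is 1 library, blue for control and orange for periodontitis, bars are group means, and the neuron list lies between 4.63 and 6.34 in 5 libraries and at most at 0.72 in the rest.

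At 0 d, cytokine and chemokine genes were higher in periodontitis than in control, while genes of red cells, B cells and dividing cells were lower. The test called 1547 genes, 899 higher and 648 lower. Of 18 cytokine and chemokine genes, 10 were higher and 0 lower (13 and 0 adjusted over the list). The median was 2.19, with camera adjusted p = 1.79e-15 and adjusted p = 0.131 with an estimated correlation. Ccl3, a chemokine that attracts myeloid cells, rose by 4.13 ± 0.70 (adjusted p = 0.00568), from 9.02 ± 1.15 CPM to 158 ± 58.2 CPM. Il1a, an alarm cytokine released by damaged cells, rose by 3.32 ± 0.53 (adjusted p = 0.00491). Osm, a cytokine of the interleukin-6 family made by myeloid cells, rose by 1.47 ± 0.21 (adjusted p = 0.00326). The classical inflammatory cytokine genes Il1b (2.23 ± 0.56, adjusted p = 0.0283) and Tnf (2.41 ± 0.43, adjusted p = 0.00687) rose, whereas Il6 did not pass (0.34 ± 0.58, adjusted p = 0.765). Of 16 interferon response genes, 2 were higher and 0 lower (5 and 0 adjusted over the list). The median was 0.61, with camera adjusted p = 4.19e-06 and adjusted p = 0.619 with an estimated correlation. Among them were the chemokine gene Cxcl10 (1.70 ± 0.42, adjusted p = 0.0266) and the guanylate-binding protein gene Gbp2 (1.37 ± 0.26, adjusted p = 0.00928).

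Blood-lineage genes fell at 0 d. Of 14 erythroid genes, 0 were higher and 8 lower (0 and 14 adjusted over the list). The median was -2.07, with camera adjusted p = 2.03e-13 and adjusted p = 0.131 with an estimated correlation. Alas2, the first enzyme of haem synthesis in red cell precursors, fell by 1.49 ± 0.25 (adjusted p = 0.00551), from 259 ± 68.1 CPM to 92.4 ± 18.6 CPM. The haemoglobin gene Hba-a1, which can share reads with a near-identical copy, fell as well (-1.65 ± 0.29, adjusted p = 0.00687). Of 15 B cell and plasma cell genes, 0 were higher and 8 lower (0 and 11 adjusted over the list). The median was -1.61, with camera adjusted p = 5.24e-11 and adjusted p = 0.360 with an estimated correlation. Cd79a, part of the B cell receptor complex, was at -1.96 ± 0.42, adjusted p = 0.0148. Epx, a granule protein gene of eosinophils, was lower too (-2.95 ± 0.76, adjusted p = 0.0315), as was Ccr2, a receptor of inflammatory monocytes (-1.36 ± 0.31, adjusted p = 0.0205). The monocyte and macrophage list was not called (median 0.16, camera adjusted p = 0.885). Of 16 cell cycle genes, 0 were higher and 9 lower (0 and 13 adjusted over the list). The median was -0.79, with camera adjusted p = 5.34e-08 and adjusted p = 0.619 with an estimated correlation. Mcm2, a subunit of the replication helicase (-0.95 ± 0.22, adjusted p = 0.0227), and Rrm2, a subunit of ribonucleotide reductase (-0.99 ± 0.25, adjusted p = 0.0286), were among those that fell. Neutrophil genes fell as a list with no single member past the test (median -0.98, camera adjusted p = 0.00620, adjusted p = 0.694 with an estimated correlation).

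Neuronal genes were among the largest rises at 0 d, in a group with 2 of 3 libraries rich in ganglion transcripts and Vip at 20.6 CPM in the third. Vip stood at 389 ± 366 CPM against 0.0424 CPM in control (adjusted p = 0.0277). Nrsn1, a neuronal vesicle protein gene, stood at 43.9 ± 41.1 CPM against 0.0627 CPM (adjusted p = 0.0364), and Nos1, the neuronal nitric oxide synthase gene, rose by 8.26 ± 2.27 (adjusted p = 0.0388). Of the 18 autonomic ganglion genes, 8 were higher and 0 lower (median 7.57). Of 8 sensory ganglion genes 0 were higher (median 1.97). Of 12 Schwann cell genes, 2 were higher and 0 lower (4 and 0 adjusted over the list). The median was 1.14, with camera adjusted p = 6.71e-04 and adjusted p = 0.677 with an estimated correlation. These are genes of the glia that wrap nerves, such as Cdh19 (2.22 ± 0.66, adjusted p = 0.0496), and their median turned to -0.16 with the neuron list as a covariate. Of 15 skeletal muscle genes, 5 were higher and 0 lower (14 and 0 adjusted over the list). The median was 3.42, with camera adjusted p = 4.20e-07 and adjusted p = 0.619 with an estimated correlation. Ttn, the giant spring protein of the sarcomere, rose by 3.71 ± 0.97 (adjusted p = 0.0329), and Actn3, an actin crosslinker of fast fibres, rose by 1.36 ± 0.32 (adjusted p = 0.0220).

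Other lists moved less at 0 d, with rises for fibroblast and wound matrix (median 0.34), matrix protease (0.33), osteoclast (0.45) and mitochondrially encoded (0.32). Camera adjusted p lay between 0.00355 and 0.0127 for these lists, and adjusted p between 0.677 and 0.694 with an estimated correlation. Thy1, a surface protein of fibroblasts and neurons, rose by 2.50 ± 0.41 (adjusted p = 0.00491), but did not pass with the neuron covariate (1.49). Mmp3, or stromelysin, rose by 2.37 ± 0.55 (adjusted p = 0.0209). Oscar, a co-stimulatory receptor of osteoclasts, was higher (0.84 ± 0.21, adjusted p = 0.0282), and Car2, a carbonic anhydrase that red cells also hold, was lower (-1.90 ± 0.39, adjusted p = 0.0134). Ambn, which encodes the enamel matrix protein ameloblastin (GRCm38 chromosome 5, 88455991 to 88468531), fell by 3.47 ± 0.68 (adjusted p = 0.0106), from 19.0 ± 19.8 CPM to 1.71 ± 1.14 CPM. Odam, expressed by maturing ameloblasts and the epithelium attached to the tooth, fell by 3.64 ± 0.98 (adjusted p = 0.0372). Dspp fell by 8.43 ± 1.84 (adjusted p = 0.0166), from 202 ± 335 CPM, most of it in 1 library, to 0.554 ± 0.900 CPM. The ameloblast and odontoblast list was not called (median -3.64, camera adjusted p = 0.149). Bglap, or osteocalcin, whose reads can be shared with Bglap2, fell by 1.24 ± 0.34 (adjusted p = 0.0396), and Mepe, an osteocyte matrix gene, fell by 0.998 ± 0.24 (adjusted p = 0.0260). Other textbook bone genes did not pass: Runx2 -0.28 ± 0.17, Sp7 -0.036 ± 0.13, Col1a1 0.38 ± 0.36, Acp5 0.44 ± 0.21 and Ctsk 0.62 ± 0.20.

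The count at 0 d was 2686 with DESeq2, 992 with the muscle list as a covariate and 65 with only these 6 libraries fitted. In settings chosen after seeing the data it was 190 with the neuron list as a covariate, 0 with neuron and muscle lists together as covariates and 63 without the 5 neuron-rich libraries. The last leaves 1 periodontitis library at 0 d and 1 at 3 d, so its loss of calls cannot be read as an effect of neuronal transcripts. It was 316 without control 0 d replicate 2, 351 without control replicate 3, 258 without periodontitis replicate 1 and 614 without periodontitis replicate 3. Of the called genes named for this comparison, 10 of 32 passed whichever library was left out: Ccl3, Il1a, Thy1, Tnf, Osm, Gbp2, Alas2, Hba-a1, Nop2 and Polr1b. Without control replicate 1 Ambn was at -2.12 and passed, but it did not without periodontitis replicate 1. Epx was at -1.58 and Rrm2 at -0.60 without control replicate 3 and Ttn at 2.20 without periodontitis replicate 3, and did not pass. With the neuron covariate Thy1, Alas2 (-1.46) and Hba-a1 (-1.32) lost their calls, and with both covariates all 10 did. Nop2 and Polr1b are genes of ribosome biogenesis.

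**Figure D2:**
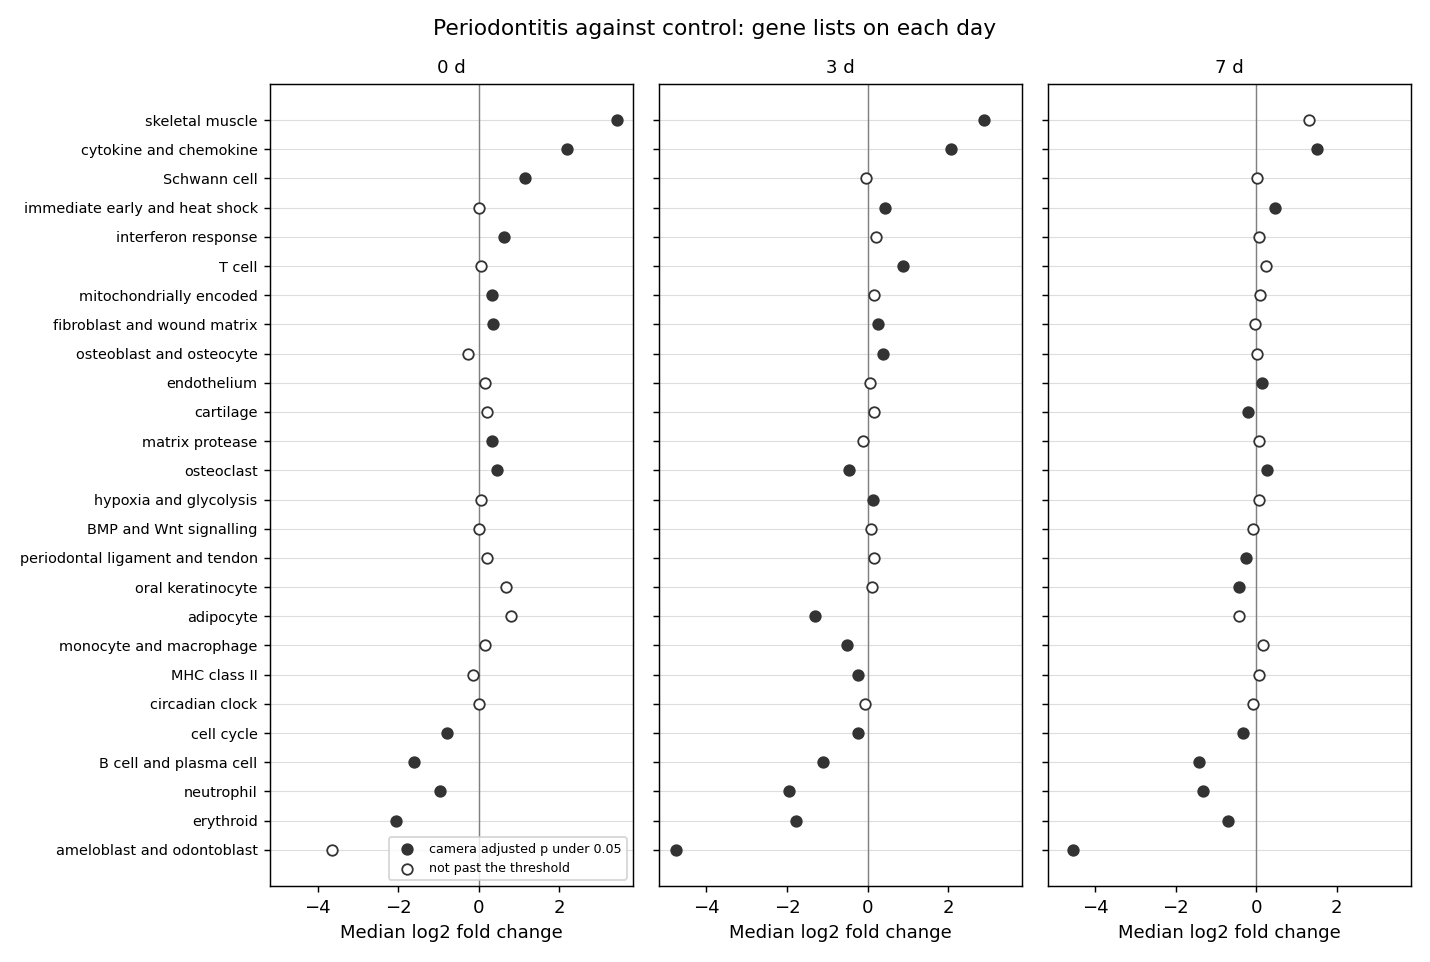
Median log2 fold change of periodontitis against control (horizontal axes) for each of the 26 tested gene lists (vertical axis) at 0 d, 3 d and 7 d. Filled points passed camera at its preset correlation and open points did not, and the cytokine and chemokine list lies at 2.19, 2.08 and 1.51 on the 3 days and the neutrophil list at -0.98, -1.94 and -1.32.

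At 3 d, the myeloid receptor genes Clec4e, Ccrl2 and Cd14 were higher in periodontitis, and the platelet genes Itga2b and Clec1b and the enamel gene Ambn were lower. The test called 25 genes, 13 higher and 12 lower. Clec4e, a receptor of macrophages and neutrophils for microbial glycolipids, rose by 2.01 ± 0.29 (adjusted p = 0.0361), from 17.4 ± 5.74 CPM to 70.3 ± 2.16 CPM. Ccrl2, a chemerin-binding receptor of activated neutrophils (2.15 ± 0.33, adjusted p = 0.0370), and Cd14, the co-receptor for bacterial endotoxin (1.76 ± 0.33, adjusted p = 0.0496), rose too. Osm rose by 1.31 ± 0.22 (adjusted p = 0.0388), and Ctla4, an inhibitory receptor of T cells, rose by 2.85 ± 0.47 (adjusted p = 0.0388). Panx3, a channel gene of osteoblasts, rose by 0.99 ± 0.18 (adjusted p = 0.0405). Among the falls were Itga2b, the platelet integrin subunit (-2.20 ± 0.38, adjusted p = 0.0388), and Clec1b, the podoplanin receptor of platelets (-2.03 ± 0.36, adjusted p = 0.0405). Ambn fell by 5.03 ± 0.79 (adjusted p = 0.0370), from 9.94 ± 2.91 CPM to 0.298 ± 0.161 CPM. Sall3, a zinc finger transcription factor, was at 1.60 ± 0.473 CPM in control and at 0 CPM in periodontitis. Slpi, an inhibitor of neutrophil elastase, fell as well (-2.35 ± 0.38, adjusted p = 0.0381).

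Several gene lists were called between the arms at 3 d with camera at its preset correlation, where few single genes passed. Among 18 cytokine and chemokine genes, 1 were higher and 0 lower (13 and 0 adjusted over the list). The median was 2.08, with camera adjusted p = 1.23e-23 and adjusted p = 0.0673 with an estimated correlation. Il1b (2.28 ± 0.56, adjusted p = 0.134), Tnf (1.52 ± 0.43, adjusted p = 0.199) and Il6 (1.41 ± 0.69, adjusted p = 0.632) did not pass over all genes. Among 15 neutrophil genes, 1 were higher and 0 lower (1 and 12 adjusted over the list). The median was -1.94, with camera adjusted p = 1.42e-09 and adjusted p = 0.243 with an estimated correlation. The member that rose was Csf3r, the receptor for granulocyte colony-stimulating factor (1.06 ± 0.20, adjusted p = 0.0496). Among 14 erythroid genes, 0 were higher and 0 lower (0 and 11 adjusted over the list). The median was -1.78, with camera adjusted p = 2.49e-09 and adjusted p = 0.232 with an estimated correlation. Falls were also called for ameloblast and odontoblast (median -4.77), adipocyte (-1.30), B cell and plasma cell (-1.10), monocyte and macrophage (-0.50), osteoclast (-0.46), MHC class II (-0.25) and cell cycle (-0.24). For these lists camera gave adjusted p from 6.46e-08 to 0.0479, and adjusted p from 0.224 to 0.572 with an estimated correlation. Rises were called for T cell (median 0.87), immediate early and heat shock (0.42), osteoblast and osteocyte (0.37), fibroblast and wound matrix (0.26) and hypoxia and glycolysis (0.14), and for skeletal muscle (2.89), whose level was high in periodontitis replicate 3. Adjusted p from camera ran from 3.17e-04 to 0.00895 here, with adjusted p from 0.243 to 0.597 with an estimated correlation. The other textbook genes did not pass: Sp7 0.37 ± 0.13, Runx2 0.23 ± 0.17, Bglap 0.35 ± 0.34, Col1a1 0.39 ± 0.36, Acp5 -0.35 ± 0.21 and Ctsk -0.42 ± 0.20.

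The count at 3 d was 291 with DESeq2, 149 with only these 6 libraries fitted, 133 without a low-count filter, 39 with a stricter filter and 0 with the muscle covariate. With the replicate block it was 53, 15 higher and 38 lower. In settings chosen after seeing the data it was 44 with the neuron covariate, 0 with both covariates, 56 with neuron-associated genes removed and 0 without the neuron-rich libraries, where 1 periodontitis library is left. It was 0 without control 3 d replicate 1, 2 without replicate 2, 13 without replicate 3, and 0, 0 and 0 without periodontitis 3 d replicate 1, 2 and 3. None of the genes named at 3 d passed in every such fit.

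At 7 d no gene passed in edgeR's quasi-likelihood test, while lists of blood, tooth and cytokine genes were called by camera at its preset correlation. The quasi-likelihood test called 0 genes, 1188 genes had an unadjusted p under 0.05, and DESeq2 called 112. The smallest adjusted p was 0.0767, shared by several genes, among them Vit, an extracellular matrix gene (-1.96 ± 0.32), Hlf, a clock output gene (-1.29 ± 0.23), and Pthlh, the parathyroid hormone-related protein gene (-3.14 ± 0.55). Sall3, with the same adjusted p, was at 1.98 ± 0.693 CPM in control and 0.0617 CPM in periodontitis. Of 15 B cell and plasma cell genes, 0 were higher and 0 lower (0 and 9 adjusted over the list). The median was -1.41, with camera adjusted p = 2.11e-13 and adjusted p = 0.321 with an estimated correlation. Of 15 neutrophil genes, 0 were higher and 0 lower (0 and 6 adjusted over the list). The median was -1.32, with camera adjusted p = 4.20e-14 and adjusted p = 0.321 with an estimated correlation. Of 18 cytokine and chemokine genes, 0 were higher and 0 lower (10 and 0 adjusted over the list). The median was 1.51, with camera adjusted p = 3.78e-08 and adjusted p = 0.327 with an estimated correlation. Il1b was at 1.93 ± 0.57, adjusted p = 0.444, Il6 at 1.74 ± 0.77, adjusted p = 0.744 and Tnf at 1.33 ± 0.47, adjusted p = 0.627. Falls were also called for ameloblast and odontoblast (median -4.54), erythroid (-0.69), oral keratinocyte (-0.43), cell cycle (-0.33), periodontal ligament and tendon (-0.25) and cartilage (-0.20), and rises for immediate early and heat shock (median 0.47), osteoclast (0.27) and endothelium (0.15). Across these lists camera adjusted p ranged from 7.43e-05 to 0.0362, and adjusted p from 0.327 to 0.497 with an estimated correlation. The lists that rose were lower in control replicates 2 and 3 and periodontitis replicate 2 than in the other libraries of 7 d (camera adjusted p at most 0.0117), and without control replicate 3 endothelium (-0.025) and immediate early and heat shock (0.32) were not called. Bone genes did not pass: Sp7 0.040 ± 0.13, Runx2 -0.0023 ± 0.17, Bglap -0.014 ± 0.34, Col1a1 -0.095 ± 0.36, Acp5 0.12 ± 0.21 and Ctsk 0.17 ± 0.20. Without a low-count filter 40 genes passed, and 2 without the neuron-rich libraries, a setting chosen after seeing the data. Without control replicate 1 or periodontitis replicate 3 of 7 d 1 gene passed.

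Averaged over the 3 days, cytokine and chemokine genes were higher in periodontitis, and the fixed lists of neutrophil, B cell, erythroid and tooth genes were lower. The test called 873 genes, 375 higher and 498 lower. Among 18 cytokine and chemokine genes, 13 were higher and 0 lower (17 and 0 adjusted over the list). The median was 1.81, with camera adjusted p = 2.01e-20 and adjusted p = 0.112 with an estimated correlation. Il1a (2.81 ± 0.33, adjusted p = 7.03e-04), Il1b (2.14 ± 0.33, adjusted p = 0.00232) and Tnf (1.75 ± 0.26, adjusted p = 0.00171) rose, while Il6 did not pass (1.16 ± 0.40, adjusted p = 0.108). Il1b stood at 251 ± 42.4 CPM in control and 1177 ± 403 CPM in periodontitis at 0 d, and at 15.9 ± 13.5 CPM and 60.3 ± 38.6 CPM at 7 d (GRCm38 chromosome 2, 129364570 to 129371139). Il1rn, the natural antagonist of the interleukin-1 receptor, rose by 1.81 ± 0.22 (adjusted p = 7.03e-04), and Nlrp3, the inflammasome sensor, rose by 1.65 ± 0.20 (adjusted p = 7.03e-04). Mmp12, the macrophage elastase, rose by 1.997 ± 0.35 (adjusted p = 0.00449), and Rspo3, an enhancer of Wnt signalling, rose by 1.49 ± 0.22 (adjusted p = 0.00185). Among 15 neutrophil genes, 1 were higher and 11 lower (1 and 12 adjusted over the list). The median was -1.51, with camera adjusted p = 9.32e-11 and adjusted p = 0.275 with an estimated correlation. Camp, the antimicrobial peptide of secondary granules, fell by 2.20 ± 0.36 (adjusted p = 0.00323). S100a9, a subunit of calprotectin, fell by 1.41 ± 0.24 (adjusted p = 0.00446). Csf3r rose by 0.51 ± 0.11 (adjusted p = 0.0189).

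B cell and plasma cell, red cell and tooth genes were lower in the mean of days. Among 15 B cell and plasma cell genes, 0 were higher and 9 lower (0 and 14 adjusted over the list). The median was -1.28, with camera adjusted p = 4.07e-14 and adjusted p = 0.195 with an estimated correlation. Cd79a fell by 1.81 ± 0.25 (adjusted p = 0.00136). Among 14 erythroid genes, 0 were higher and 9 lower (0 and 14 adjusted over the list). The median was -1.54, with camera adjusted p = 2.50e-12 and adjusted p = 0.168 with an estimated correlation. Among 7 ameloblast and odontoblast genes, 0 were higher and 5 lower (0 and 5 adjusted over the list). The median was -3.88, with camera adjusted p = 1.07e-04 and adjusted p = 0.275 with an estimated correlation. Ambn fell by 3.71 ± 0.42 (adjusted p = 6.39e-04) and Odam fell by 3.88 ± 0.61 (adjusted p = 0.00269). Cell cycle genes fell (median -0.46, camera adjusted p = 7.93e-10, adjusted p = 0.292 with an estimated correlation). Myh2, a myosin gene of fast muscle fibres, rose by 6.75 ± 1.44 (adjusted p = 0.0147) in a skeletal muscle list that rose (median 2.57, camera adjusted p = 1.07e-04, adjusted p = 0.598 with an estimated correlation). Smaller rises were called for immediate early and heat shock (median 0.36), interferon response (0.26), mitochondrially encoded (0.18), fibroblast and wound matrix (0.17), endothelium (0.12) and matrix protease (0.078). Camera adjusted p lay between 8.36e-04 and 0.0341 for these lists, and adjusted p between 0.598 and 0.609 with an estimated correlation. The remaining textbook genes did not pass: Sp7 0.13 ± 0.074, Runx2 -0.018 ± 0.10, Bglap -0.30 ± 0.20, Col1a1 0.23 ± 0.21, Acp5 0.071 ± 0.12 and Ctsk 0.12 ± 0.12.

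The count for the mean of days was 1601 with DESeq2, 286 with the muscle covariate and, in settings chosen after seeing the data, 217 without the neuron-rich libraries and 10 with both covariates. It was 548 without control 0 d replicate 2, 524 without control 3 d replicate 3 and 513 without control 7 d replicate 2. It was 578, 458, 565 and 495 without periodontitis 0 d replicate 1, 3 d replicate 1, 3 d replicate 3 and 7 d replicate 1. The majority of calls turned from lower to higher in several settings, with 434 and 408 higher and lower with RLE size factors and 513 and 447 with at least 1 CPM in 9 libraries. They were 403 and 354 with the muscle, erythroid, salivary and tooth lists removed, 497 and 490 without a low-count filter and 838 and 763 with DESeq2. Myh2 was at 3.92 without periodontitis 7 d replicate 1 and at 4.60 without 3 d replicate 3, and did not pass. Among called genes named here 18 of 19 passed in every fit without 1 library.

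**Figure D3:**
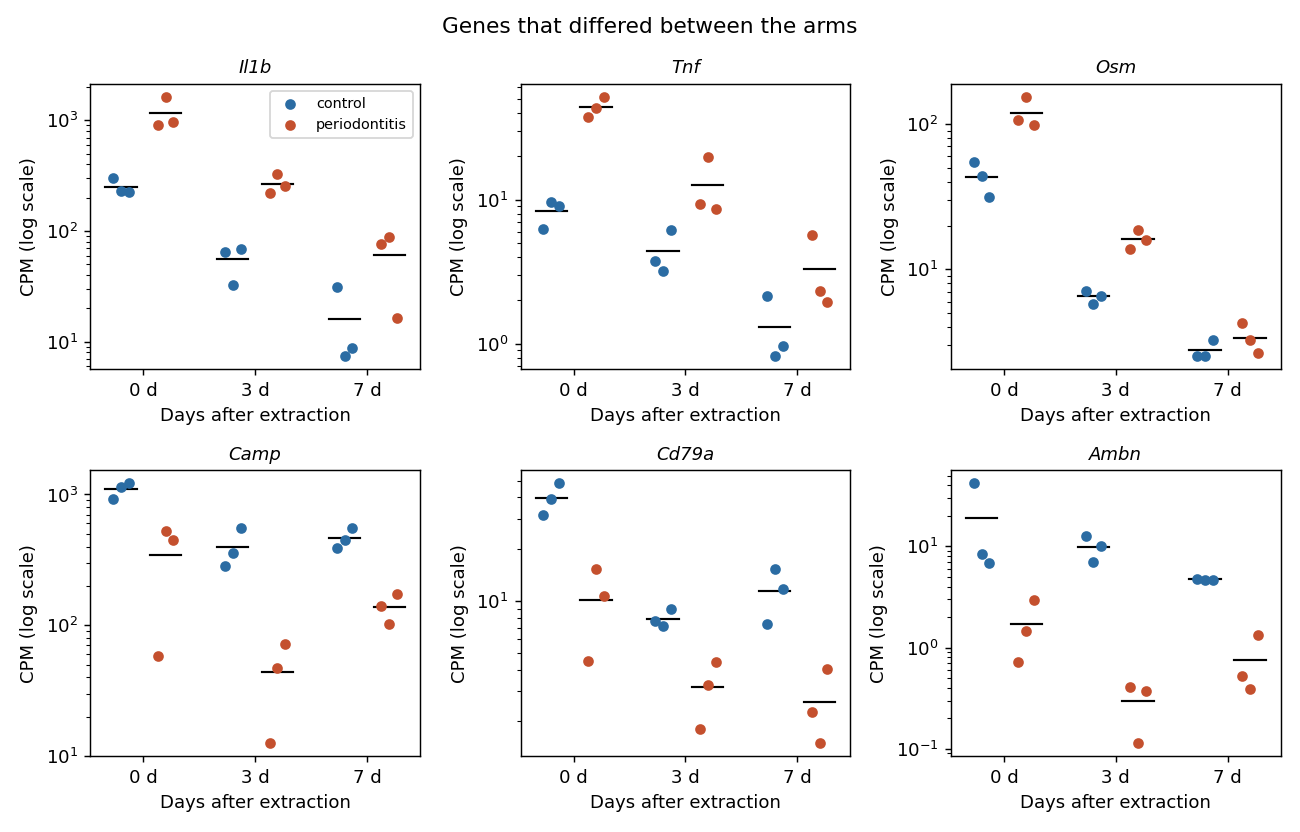
CPM on a log scale (vertical axes) of Il1b, Tnf, Osm, Camp, Cd79a and Ambn against days after extraction (horizontal axes). Each point is 1 library, blue for control and orange for periodontitis, bars are group means, and Ambn lies at 19.0, 9.94 and 4.71 CPM in control and at 1.71, 0.298 and 0.748 CPM in periodontitis on the 3 days.

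Between 0 d and 3 d in control, genes of red cells, interferon response, cytokines and the immediate early response fell and osteoclast genes rose. The test called 6488 genes, 3062 higher and 3426 lower. Of 14 erythroid genes, 0 were higher and 14 lower (0 and 14 adjusted over the list). The median was -4.33, with camera adjusted p = 8.60e-11 and adjusted p = 0.460 with an estimated correlation. Alas2 fell by 4.76 ± 0.29 (adjusted p = 5.67e-08). Of 16 interferon response genes, 0 were higher and 14 lower (0 and 14 adjusted over the list). The median was -2.25, with camera adjusted p = 8.76e-11 and adjusted p = 0.460 with an estimated correlation. Rsad2, or viperin, fell by 4.37 ± 0.30 (adjusted p = 1.76e-07). Of 18 cytokine and chemokine genes, 1 were higher and 13 lower (1 and 13 adjusted over the list). The median was -2.07, with camera adjusted p = 7.40e-06 and adjusted p = 0.650 with an estimated correlation. Il6 fell by 5.73 ± 0.74 (adjusted p = 3.60e-05), and so did the neutrophil chemokine gene Cxcl1 (-5.05 ± 0.65, adjusted p = 3.58e-05) and Il1b (-2.18 ± 0.56, adjusted p = 0.00684), while Tnf did not pass (-0.93 ± 0.43, adjusted p = 0.106). Of 15 osteoclast genes, 12 were higher and 2 lower (12 and 2 adjusted over the list). The median was 0.97, with camera adjusted p = 1.45e-04 and adjusted p = 0.792 with an estimated correlation. Atp6v0d2, a subunit of the proton pump that acidifies the resorption pit, rose by 1.64 ± 0.23 (adjusted p = 7.83e-05). Ctsk, the collagen-degrading protease cathepsin K, rose by 1.26 ± 0.20 (adjusted p = 2.40e-04), and Acp5, the tartrate-resistant acid phosphatase, rose by 0.79 ± 0.21 (adjusted p = 0.00786).

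Falls between 0 d and 3 d in control were also called for B cell and plasma cell (median -2.19), immediate early and heat shock (-1.81) and neutrophil (-1.57). For these lists camera gave adjusted p from 2.05e-06 to 2.97e-04, and adjusted p from 0.460 to 0.808 with an estimated correlation. Cd79a fell by 2.33 ± 0.43 (adjusted p = 5.93e-04), Cxcr2, a chemokine receptor of neutrophils, fell by 2.53 ± 0.29 (adjusted p = 1.16e-05), and Dusp1, an early-response phosphatase, fell by 2.47 ± 0.29 (adjusted p = 1.52e-05). Acta2, the smooth muscle actin of myofibroblasts, rose by 2.91 ± 0.44 (adjusted p = 1.31e-04), and Mmp11 rose by 2.72 ± 0.22 (adjusted p = 5.54e-07). The osteocyte matrix gene Dmp1 fell by 2.38 ± 0.30 (adjusted p = 2.59e-05) and Bglap fell by 1.60 ± 0.35 (adjusted p = 0.00218). Sp7, the osteoblast transcription factor osterix, rose by 0.56 ± 0.13 (adjusted p = 0.00297), while Runx2 (-0.37 ± 0.17) and Col1a1 (0.30 ± 0.36) did not pass. Vip was at 0.0424 CPM and then at 113 ± 193 CPM, which rests on control 3 d replicate 2. With library totals in place of TMM all genes shifted by a median of 0.12, and the calls split into 3805 higher and 2589 lower. Of the called genes named for this comparison, 16 of the 16 passed in every fit without 1 library.

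Between 0 d and 7 d in control, ligament and tendon genes and the osteoblast gene Sp7 rose, and cytokine, cell cycle and glycolytic genes fell. The test called 7726 genes, 3731 higher and 3995 lower. Among 13 periodontal ligament and tendon genes, 7 were higher and 1 lower (7 and 1 adjusted over the list). The median was 0.73, with camera adjusted p = 0.0261 and adjusted p = 0.622 with an estimated correlation. Ogn, a small matrix proteoglycan gene, rose by 1.96 ± 0.28 (adjusted p = 5.56e-05). Sp7 rose by 1.11 ± 0.13 (adjusted p = 7.39e-06). Ctsk rose by 0.99 ± 0.20 (adjusted p = 0.00105) and Acp5 rose by 0.71 ± 0.21 (adjusted p = 0.0118). Bglap (0.18 ± 0.34), Runx2 (-0.086 ± 0.17) and Col1a1 (0.25 ± 0.36) did not pass. The BMP and Wnt signalling list was not called, with 6 higher and 3 lower of 18 (median 0.38, camera adjusted p = 0.330). Among 18 cytokine and chemokine genes, 0 were higher and 16 lower (0 and 16 adjusted over the list). The median was -3.83, with camera adjusted p = 1.04e-07 and adjusted p = 0.315 with an estimated correlation. Il6 (-6.80 ± 0.80, adjusted p = 8.38e-06) and Ptgs2, the inducible cyclooxygenase gene (-6.06 ± 0.65, adjusted p = 3.47e-06), fell, and so did Il1b (-3.99 ± 0.61, adjusted p = 9.54e-05) and Tnf (-2.66 ± 0.47, adjusted p = 3.32e-04). Among 16 cell cycle genes, 0 were higher and 12 lower (0 and 14 adjusted over the list). The median was -0.99, with camera adjusted p = 1.78e-04 and adjusted p = 0.628 with an estimated correlation. Rrm2 fell by 1.69 ± 0.25 (adjusted p = 8.17e-05).

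Falls between 0 d and 7 d in control were also called for erythroid (median -4.28), immediate early and heat shock (-2.71), interferon response (-2.46), B cell and plasma cell (-1.50), neutrophil (-1.40), circadian clock (-1.07), MHC class II (-0.95) and hypoxia and glycolysis (-0.74). Adjusted p from camera ran from 3.71e-10 to 0.00920 here, with adjusted p from 0.268 to 0.659 with an estimated correlation. Alas2 fell by 4.39 ± 0.28 (adjusted p = 3.61e-08) and Rsad2 fell by 4.03 ± 0.30 (adjusted p = 1.03e-07). The immediate early gene Junb fell by 2.86 ± 0.25 (adjusted p = 4.42e-07), the glycolytic enzyme gene Hk2 fell by 2.88 ± 0.19 (adjusted p = 3.78e-08), and Cd74, the invariant chain of MHC class II, fell by 1.42 ± 0.30 (adjusted p = 0.00124). Per2, a repressor of the circadian clock, fell by 2.43 ± 0.22 (adjusted p = 6.62e-07). Dmbt1, a secreted glycoprotein gene of salivary ducts, rose from 0.0636 CPM to 113 ± 193 CPM (adjusted p = 0.0131), but did not pass without control 7 d replicate 3 (log2 4.20), the library with the most salivary gland transcripts. With library totals all genes shifted by a median of 0.14, and the calls split into 4658 higher and 3143 lower. Among called genes named here 15 of 16 passed in every fit without 1 library.

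From 3 d to 7 d in control, cell cycle and cytokine genes fell, and osteoblast and osteocyte genes and ligament and tendon genes rose. The test called 2030 genes, 933 higher and 1097 lower. Of 15 osteoblast and osteocyte genes, 4 were higher and 0 lower (8 and 0 adjusted over the list). The median was 0.37, with camera adjusted p = 3.01e-04 and adjusted p = 0.558 with an estimated correlation. Phex, an osteocyte peptidase that regulates phosphate, rose by 1.94 ± 0.30 (adjusted p = 0.00247). Bglap (1.78 ± 0.35, adjusted p = 0.00719) and Sp7 (0.55 ± 0.13, adjusted p = 0.0148) rose as well. Of 13 periodontal ligament and tendon genes, 5 were higher and 0 lower (7 and 0 adjusted over the list). The median was 0.89, with camera adjusted p = 7.67e-04 and adjusted p = 0.541 with an estimated correlation. Tnmd, a tendon marker, rose by 1.05 ± 0.19 (adjusted p = 0.00558). Of 16 cell cycle genes, 0 were higher and 12 lower (0 and 15 adjusted over the list). The median was -1.03, with camera adjusted p = 3.02e-11 and adjusted p = 0.541 with an estimated correlation. Mcm2 fell by 1.45 ± 0.23 (adjusted p = 0.00247). Of 18 cytokine and chemokine genes, 0 were higher and 7 lower (0 and 12 adjusted over the list). The median was -1.63, with camera adjusted p = 1.05e-05 and adjusted p = 0.541 with an estimated correlation. Osm (-1.23 ± 0.25, adjusted p = 0.00757) and Tnf (-1.73 ± 0.47, adjusted p = 0.0298) fell, and Il1b (-1.80 ± 0.57) and Il6 (-1.07 ± 0.80) did not pass. Nfatc1, the master factor of osteoclasts, fell by 1.13 ± 0.21 (adjusted p = 0.00483), while Acp5 (-0.078 ± 0.21), Ctsk (-0.27 ± 0.20), Runx2 (0.29 ± 0.17) and Col1a1 (-0.056 ± 0.36) did not pass.

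Falls from 3 d to 7 d in control were also called for ameloblast and odontoblast (median -1.44), immediate early and heat shock (-0.74), hypoxia and glycolysis (-0.68), osteoclast (-0.51), matrix protease (-0.42) and MHC class II (-0.42), and a rise for mitochondrially encoded (median 0.54). Across these lists camera adjusted p ranged from 1.82e-04 to 0.0352, and adjusted p from 0.458 to 0.558 with an estimated correlation. Mitochondrially encoded genes took 3.21% and 2.68% of counts in control 7 d replicates 2 and 3, against 1.73% in replicate 1 and at most 1.86% at 3 d. Plau, a plasminogen activator gene, fell by 1.56 ± 0.30 (adjusted p = 0.00682), and Pgk1, a glycolytic enzyme gene, fell by 0.85 ± 0.10 (adjusted p = 6.33e-04). Arntl, which encodes the clock activator BMAL1, rose by 1.83 ± 0.15 (adjusted p = 4.24e-05). The count was 3064 with DESeq2, 1075 with these 6 libraries alone and 243 without the neuron-rich libraries, a setting chosen after seeing the data. It was 881, 1006 and 961 without control 3 d replicate 1, 2 and 3, and 3495, 414 and 477 without control 7 d replicate 1, 2 and 3. Of the called genes named for this comparison, 9 of the 11 passed in all of these fits.

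**Figure D4:**
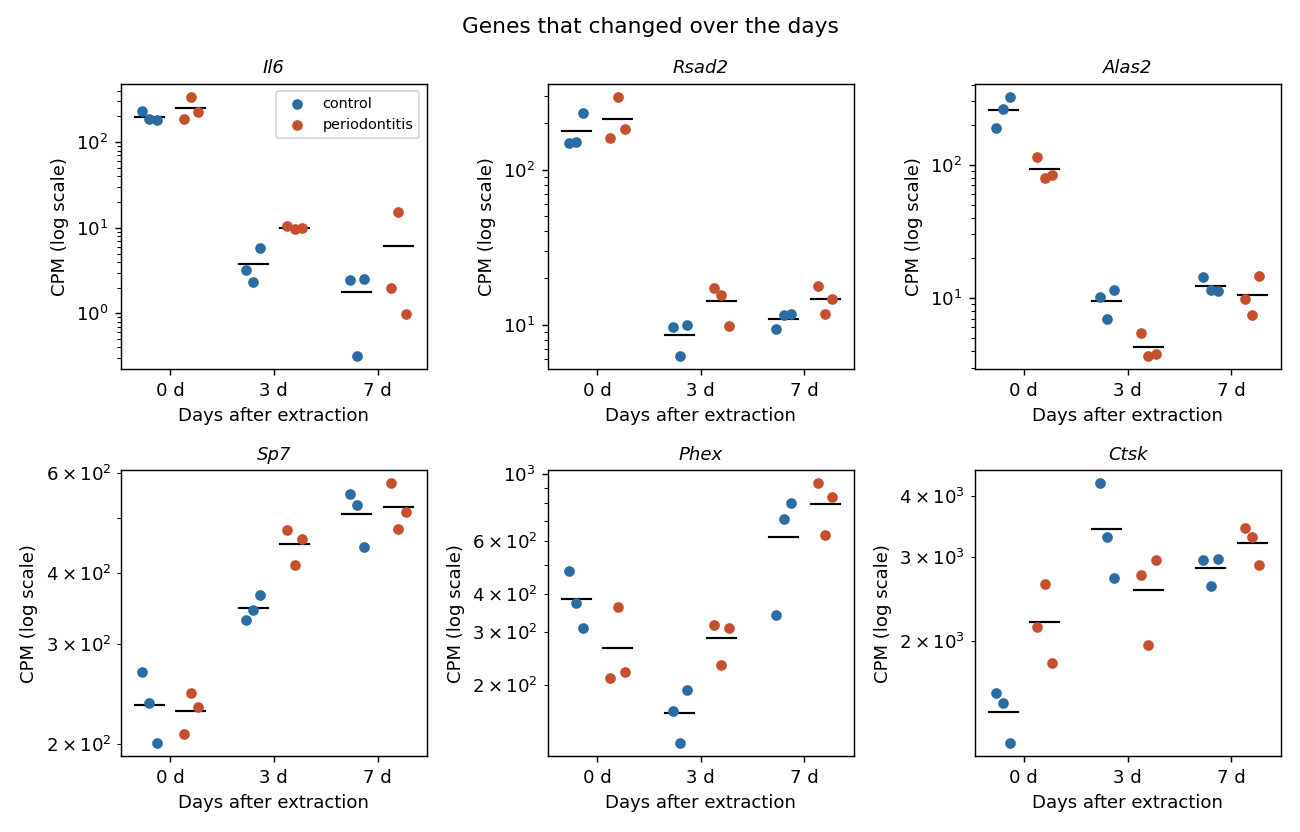
CPM on a log scale (vertical axes) of Il6, Rsad2, Alas2, Sp7, Phex and Ctsk against days after extraction (horizontal axes). Each point is 1 library, blue for control and orange for periodontitis, bars are group means, and Sp7 lies at 235, 347 and 508 CPM in control and at 229, 449.5 and 522 CPM in periodontitis on the 3 days.

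In periodontitis, interferon, cytokine and red cell genes fell between 0 d and 3 d and cell cycle genes rose. The test called 3967 genes, 1686 higher and 2281 lower. Among 16 interferon response genes, 0 were higher and 16 lower (0 and 16 adjusted over the list). The median was -2.62, with camera adjusted p = 4.92e-19 and adjusted p = 0.192 with an estimated correlation. Rsad2 fell by 3.91 ± 0.29 (adjusted p = 1.00e-06). Among 18 cytokine and chemokine genes, 0 were higher and 16 lower (0 and 16 adjusted over the list). The median was -2.29, with camera adjusted p = 1.02e-11 and adjusted p = 0.192 with an estimated correlation. Ccl2, a monocyte chemokine, fell by 3.54 ± 0.49 (adjusted p = 1.29e-04). Il6 (-4.66 ± 0.69, adjusted p = 2.16e-04), Il1b (-2.13 ± 0.56, adjusted p = 0.0127) and Tnf (-1.82 ± 0.42, adjusted p = 0.00592) fell too. Among 16 cell cycle genes, 4 were higher and 0 lower (4 and 0 adjusted over the list). The median was 0.58, with camera adjusted p = 1.46e-04 and adjusted p = 0.694 with an estimated correlation. Mcm2 rose by 0.84 ± 0.22 (adjusted p = 0.0147), Sp7 rose by 0.97 ± 0.13 (adjusted p = 7.81e-05) and Acta2 rose by 1.49 ± 0.41 (adjusted p = 0.0179). Falls were also called for erythroid (median -4.27), skeletal muscle (-2.77), neutrophil (-2.53), adipocyte (-2.21), B cell and plasma cell (-1.53), immediate early and heat shock (-1.32), Schwann cell (-1.11), mitochondrially encoded (-0.56) and circadian clock (-0.33). Camera adjusted p lay between 2.53e-09 and 0.0206 for these lists, and adjusted p between 0.192 and 0.719 with an estimated correlation. Alas2 fell by 4.42 ± 0.30 (adjusted p = 6.40e-07), Cxcr2 fell by 1.70 ± 0.28 (adjusted p = 5.07e-04) and Ttn fell by 3.06 ± 0.93 (adjusted p = 0.0285).

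The bone genes Runx2 (0.14 ± 0.17), Bglap (-0.00028 ± 0.34), Col1a1 (0.31 ± 0.36), Acp5 (0.00083 ± 0.21) and Ctsk (0.22 ± 0.20) did not pass in periodontitis between 0 d and 3 d. With library totals all genes shifted by a median of 0.072, and the calls split into 2066 higher and 1913 lower. The count was 612 without the neuron-rich libraries, a setting chosen after seeing the data. It leaves 1 library in each of these groups, which is assumed to vary like the other groups. The count was 2520 without periodontitis 3 d replicate 1, Ttn did not pass without 0 d replicate 3 (-1.49), and 7 of the 11 called genes named for it passed in every fit without 1 library.

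Between 0 d and 7 d in periodontitis, osteoblast and osteocyte genes rose and cytokine, interferon and glycolytic genes fell. The test called 7300 genes, 3421 higher and 3879 lower. Among 15 osteoblast and osteocyte genes, 7 were higher and 0 lower (7 and 0 adjusted over the list). The median was 0.25, with camera adjusted p = 0.0221 and adjusted p = 0.691 with an estimated correlation. Sp7 (1.19 ± 0.13, adjusted p = 7.02e-06) and Bglap (1.41 ± 0.34, adjusted p = 0.00523) rose, and so did Sost, the osteocyte Wnt inhibitor sclerostin (3.48 ± 0.51, adjusted p = 1.06e-04). Ogn rose by 1.89 ± 0.28 (adjusted p = 1.21e-04). Ctsk rose by 0.55 ± 0.20 (adjusted p = 0.0425), but did not pass with RLE size factors, without a low-count filter, with these 6 libraries alone or with the neuron covariate (0.29). Acp5 (0.39 ± 0.21), Runx2 (0.19 ± 0.17) and Col1a1 (-0.23 ± 0.36) did not pass. Among 18 cytokine and chemokine genes, 0 were higher and 17 lower (0 and 17 adjusted over the list). The median was -4.24, with camera adjusted p = 3.58e-15 and adjusted p = 0.125 with an estimated correlation. Nos2, the inducible nitric oxide synthase gene, fell by 6.18 ± 0.61 (adjusted p = 2.63e-06). Il6 (-5.40 ± 0.72, adjusted p = 4.63e-05), Il1b (-4.29 ± 0.61, adjusted p = 8.56e-05) and Tnf (-3.73 ± 0.46, adjusted p = 2.12e-05) fell too. Among 16 interferon response genes, 0 were higher and 15 lower (0 and 16 adjusted over the list). The median was -3.19, with camera adjusted p = 3.58e-15 and adjusted p = 0.150 with an estimated correlation. Cxcl10 fell by 8.07 ± 0.60 (adjusted p = 2.91e-07).

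Falls between 0 d and 7 d in periodontitis were also called for adipocyte (median -3.38), skeletal muscle (-3.19), erythroid (-2.90), immediate early and heat shock (-2.19), neutrophil (-1.86), oral keratinocyte (-1.61), Schwann cell (-1.47), B cell and plasma cell (-1.20), circadian clock (-0.94), MHC class II (-0.87), matrix protease (-0.71), hypoxia and glycolysis (-0.67) and cell cycle (-0.50). For these lists camera gave adjusted p from 1.26e-08 to 0.0463, and adjusted p from 0.125 to 0.691 with an estimated correlation. The Schwann cell median became 0.046 with the neuron list as a covariate. Alas2 fell by 3.12 ± 0.27 (adjusted p = 8.90e-07), Csf3r fell by 2.31 ± 0.20 (adjusted p = 9.65e-07), and Fabp4, a fatty acid carrier, fell by 1.92 ± 0.19 (adjusted p = 3.29e-06). The glucose transporter gene Slc2a1 fell by 2.31 ± 0.25 (adjusted p = 7.26e-06). Neuronal genes were among the largest falls: Chrna3, a nicotinic receptor subunit of ganglia, stood at 40.2 ± 37.7 CPM at 0 d and 0 CPM at 7 d. The count was 4724 with these 6 libraries alone and, in settings chosen after seeing the data, 4035 with the neuron covariate and 2512 without the neuron-rich libraries. With library totals all genes shifted by a median of 0.13, and the calls split into 4513 higher and 3162 lower. Among called genes named here 13 of 14 passed in every fit without 1 library.

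From 3 d to 7 d in periodontitis, osteoblast and osteocyte genes and the clock activator gene Arntl rose and cytokine, cell cycle and glycolytic genes fell. The test called 897 genes, 406 higher and 491 lower. Of 15 osteoblast and osteocyte genes, 3 were higher and 0 lower (4 and 0 adjusted over the list). The median was 0.25, with camera adjusted p = 0.0281 and adjusted p = 0.704 with an estimated correlation. Phex rose by 1.48 ± 0.30 (adjusted p = 0.0164), Bglap rose by 1.41 ± 0.34 (adjusted p = 0.0332) and Tnmd rose by 1.30 ± 0.20 (adjusted p = 0.00435). Arntl rose by 1.40 ± 0.15 (adjusted p = 6.88e-04), and Mrc1, the mannose receptor of macrophages, rose by 0.89 ± 0.20 (adjusted p = 0.0245). Of 18 cytokine and chemokine genes, 0 were higher and 9 lower (0 and 14 adjusted over the list). The median was -1.85, with camera adjusted p = 9.13e-15 and adjusted p = 0.139 with an estimated correlation. Nos2 (-4.07 ± 0.56, adjusted p = 0.00283), Il1b (-2.15 ± 0.56, adjusted p = 0.0419) and Tnf (-1.92 ± 0.44, adjusted p = 0.0267) fell. Of 16 cell cycle genes, 0 were higher and 12 lower (0 and 14 adjusted over the list). The median was -1.10, with camera adjusted p = 3.71e-14 and adjusted p = 0.214 with an estimated correlation. Plk1, a mitotic kinase gene, fell by 1.85 ± 0.30 (adjusted p = 0.00611). Falls were also called for hypoxia and glycolysis (median -0.69), circadian clock (-0.68), immediate early and heat shock (-0.67), T cell (-0.59), interferon response (-0.47) and fibroblast and wound matrix (-0.47), and rises for erythroid (median 1.36), monocyte and macrophage (0.59) and mitochondrially encoded (0.57). Adjusted p from camera ran from 1.51e-06 to 0.0307 here, with adjusted p from 0.0737 to 0.704 with an estimated correlation. The last of these rises lost its call without periodontitis 7 d replicate 2. Il6 (-0.74 ± 0.66), Sp7 (0.22 ± 0.13), Acp5 (0.39 ± 0.21), Ctsk (0.33 ± 0.20), Runx2 (0.054 ± 0.17) and Col1a1 (-0.54 ± 0.36) did not pass.

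With library totals the calls from 3 d to 7 d in periodontitis split into 427 higher and 404 lower. The count was 2569 with DESeq2 and, in settings chosen after seeing the data, 255 with the neuron covariate and 3 without the neuron-rich libraries. It was 178, 83 and 465 without periodontitis 3 d replicate 1, 2 and 3, and 322 and 343 without 7 d replicate 1 and 2. Among called genes named here 4 of 9 passed in every such fit.

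Changes with time in the 2 arms, which share no library, were compared by the overlap of their calls and by interaction tests. Between 0 d and 3 d, 1276 genes were higher in both arms and 1847 lower in both, against 276 and 418 for independent lists, and 7 were opposite. Between 0 d and 7 d the arms shared 4851 calls with 13 opposite, and between 3 d and 7 d 600 with 0 opposite. The change from 0 d to 3 d differed between the arms for 3 genes and that from 0 d to 7 d for 8. Aplnr, the apelin receptor of vessels, went from 7.06 ± 1.63 CPM to 126 ± 13.3 CPM in control and from 48.8 ± 8.13 CPM to 159 ± 16.5 CPM in periodontitis between 0 d and 3 d (interaction -2.46 ± 0.29, adjusted p = 0.00568). Bpgm, the red cell enzyme that makes bisphosphoglycerate, and Tfpi2, a protease inhibitor gene, fell less in periodontitis (interactions 1.33 ± 0.17, adjusted p = 0.00737 and 1.49 ± 0.21, adjusted p = 0.0215). The interactions at 7 d included Aplnr (-2.56 ± 0.29, adjusted p = 0.00339), Tfpi2 (1.69 ± 0.21, adjusted p = 0.00668) and Bpgm (1.12 ± 0.17, adjusted p = 0.0200). They also included the interleukin-23 subunit gene Il23a (-3.68 ± 0.61, adjusted p = 0.0421) and the ribosome assembly genes Heatr1 (1.24 ± 0.17, adjusted p = 0.0157) and Nop16 (0.84 ± 0.13, adjusted p = 0.0330). Pus7, a pseudouridine synthase gene (1.09 ± 0.16, adjusted p = 0.0200), and Nat10, an RNA acetyltransferase gene, completed them.

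No textbook gene passed the interaction tests. At 3 d the interactions were Il1b 0.049 ± 0.76, Il6 1.07 ± 0.90, Tnf -0.89 ± 0.59, Bglap 1.60 ± 0.48, Runx2 0.51 ± 0.24, Sp7 0.41 ± 0.18, Col1a1 0.0038 ± 0.51, Acp5 -0.79 ± 0.29 and Ctsk -1.04 ± 0.29. At 7 d they were Il1b -0.30 ± 0.77, Il6 1.40 ± 0.97, Tnf -1.08 ± 0.63, Bglap 1.23 ± 0.48, Runx2 0.28 ± 0.24, Sp7 0.076 ± 0.18, Col1a1 -0.48 ± 0.51, Acp5 -0.32 ± 0.29 and Ctsk -0.45 ± 0.29. The counts at 3 d and 7 d were 214 and 712 with DESeq2, and 27 and 110 without a low-count filter. In settings chosen after seeing the data they were 5 and 1 with the neuron covariate and 0 and 0 without the neuron-rich libraries. The count at 3 d was 143 without periodontitis 0 d replicate 2, 17 without control 3 d replicate 3 and 8 without control 0 d replicate 3, and between 1 and 3 without each of the other libraries. The count at 7 d was 419 without periodontitis 0 d replicate 2, 53 without periodontitis 7 d replicate 2, 21 without control 7 d replicate 1 and 19 without control 0 d replicate 3, and between 2 and 7 without each of the other libraries. Of the called genes named for this comparison, 1 of 3 passed at 3 d and 2 of 7 at 7 d in every fit without 1 library.

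Whether the difference between arms ran along the healing course was measured as a correlation across genes. It set the arm difference on 1 day against the control change between the other days, which share no library with it. Genes are not independent replicates, so p-values came from exact permutation of the 6 libraries of the day, two-sided, with 0.1 the smallest value possible. At 0 d Pearson's r was -0.47 (Spearman's rho -0.044, exact permutation p = 0.4). At 3 d it was 0.075 (rho 0.17, exact permutation p = 0.2) and at 7 d -0.11 (rho -0.091, exact permutation p = 0.3), in a family of 3 relations. Adjusted by Benjamini-Hochberg, these exact permutation p-values were 0.4, 0.4 and 0.4. Without control 3 d replicate 2, the control library rich in neuronal transcripts, r was -0.048 at 0 d and 0.038 at 7 d. At 3 d it was 0.012 without control 0 d replicate 3, 0.044 without control 3 d replicate 2, 0.040 without control 3 d replicate 3, 0.026 without control 7 d replicate 1, 0.12 without control 7 d replicate 3 and 0.049 without periodontitis 3 d replicate 1. At 7 d it was -0.066 without control 7 d replicate 3, -0.067 without periodontitis 7 d replicate 1 and -0.067 without periodontitis 7 d replicate 3. With at least 1 CPM in 9 libraries r was -0.22, 0.16 and -0.067 on the 3 days. In settings chosen after seeing the data it was -0.18, 0.035 and 0.067 with the neuron covariate. At 0 d and 7 d it was -0.094 and -0.047 with neuron-associated genes removed, and -0.060 and 0.044 without the neuron-rich libraries.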

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

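In this part, the tests of periodontitis as the whole cause of the neuronal transcripts, of a sample swap, of fewer leukocytes of every kind, of 1 control library for Odam, Dspp and Sall3 and of the splits of samples were chosen only after the results were seen. Transcripts of autonomic ganglion neurons stood out in 5 libraries, with a mean log2 CPM of their 18 genes between 4.63 and 6.34 against at most 0.72 in the rest. The tables argue against periodontitis as the whole cause, since control 3 d replicate 2 was at 5.17. Ambn was at 6.95 CPM there and 0.373 CPM in periodontitis 3 d replicate 3. This cannot test for a swap, since named genes had to separate the labelled arms. The median of cytokine genes at 0 d was 2.19 and became 2.43 with the neuron covariate. This argues against ganglion tissue as the source of their rise. A candidate explanation for the pattern is a piece of ganglion in the dissected sample: neuron-associated genes differed alike at 3 d and 0 d (r = 0.71 across genes), but these genes were chosen for the pattern, so this source and nerve tissue of another kind or a change in the jaw itself cannot be told apart. Of the higher calls at 0 d, 26.7% were neuron-associated against 6.23% of all genes, and the erythroid and B cell median moved from -1.93 to -1.42 with the covariate; how many of the 0 d calls come from the ganglion tissue and how many from periodontitis cannot be told apart, because all 3 periodontitis libraries of that day lay above its control libraries in the mean log2 CPM of this list, replicate 2 at 0.72 against at most -0.97.

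Over the mean of days, neutrophil, erythroid and B cell lists were lower in periodontitis and cytokine genes higher. Of 8 activated neutrophil genes, 6 were higher and 0 lower (median 1.54), which partly repeats rises already seen (Il1b, Ccrl2, Clec4e). The median of the 3 blood lists, -1.47, or -1.72 with the muscle covariate, argues against dilution by skeletal muscle. The T cell list, at 0.22 (median absolute deviation 0.45), and monocyte and macrophage list, at -0.089 (0.10), against -1.51 (0.43) for the neutrophil list, argue against fewer leukocytes of every kind. Less bone marrow in the periodontitis samples may account for the falls: the 4 marrow precursor lists had medians between -1.96 and -1.30 and could have stayed near 0. Whether less marrow was collected or that of the diseased jaw held fewer precursors was not tested, and periodontitis itself stays open as the cause.

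Ambn, Odam, Dspp and Sall3 had lower mean CPM in periodontitis on each day. That control 0 d replicate 1 decides the mean of days is argued against by Ambn, whose adjusted p without it was 7.67e-04, and by Odam, Dspp and Sall3, with at most 0.00423. At 0 d alone that library matters. Without it Odam went from -3.64 ± 0.98 to -2.19 ± 0.92 (adjusted p = 0.154). Dspp went from -8.43 ± 1.84 to -3.88 ± 1.23 (adjusted p = 0.0733). Ambn went to -2.12 ± 0.53 and passed. Dental cells in control samples are a candidate explanation. They and an effect of periodontitis on tooth cells cannot be told apart, because either would lower tooth genes. A second list of 10 dental genes cannot decide, as members such as Barx1 had at least 47.9 CPM in every library. Its median was -0.14 (median absolute deviation 0.21), from -5.17 to 0.12, 8 below 0 (3 called) and 2 above (0).

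Interaction tests found changes with time that differed between the arms. Between 0 d and 3 d these were Aplnr (-2.46), Bpgm (1.33) and Tfpi2 (1.49), and between 0 d and 7 d Aplnr (-2.56), Bpgm (1.12), Tfpi2 (1.69), Heatr1 (1.24), Nat10 (0.80), Pus7 (1.09), Nop16 (0.84) and Il23a (-3.68). Il23a was at 2.88 ± 0.0933 CPM in periodontitis at 0 d and at most at 0.516 CPM on average in the other 5 groups. Lists whose change from 0 d to 3 d differed with camera were osteoclast (median -0.86), monocyte and macrophage (median -0.76), adipocyte (median -3.31), Schwann cell (median -1.19), matrix protease (median -0.41), interferon response (median -0.31), T cell (median 1.14), B cell and plasma cell (median 0.58), cell cycle (median 0.54) and osteoblast and osteocyte (median 0.21), with adjusted p from 0.567 to 0.778 with an estimated correlation. From 0 d to 7 d they were erythroid (median 1.22), fibroblast and wound matrix (median -0.38), periodontal ligament and tendon (median -0.42), interferon response (median -0.52), cell cycle (median 0.44), skeletal muscle (median -1.94), oral keratinocyte (median -1.50) and Schwann cell (median -1.23), each with adjusted p = 0.787 with an estimated correlation; the last turned to 0.15 with the neuron covariate.

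The libraries of each comparison were regrouped to ask how often other splits give as many calls. For the comparisons of 3 against 3 the 10 splits are too few for a share under 0.05; the real counts and the highest of the other splits were 1547 and 4 between arms at 0 d, 25 and 323 at 3 d, 0 and 1553 at 7 d, 6488 and 0, 7726 and 1 and 2030 and 0 for the control changes from 0 d to 3 d, 0 d to 7 d and 3 d to 7 d, and 3967 and 0, 7300 and 1 and 897 and 0 for the same changes in periodontitis. The split with 323 genes at 3 d sets control replicate 2 and periodontitis replicates 1 and 2, the neuron-rich libraries, against the rest, and points to that structure of the samples. The split with 1553 genes at 7 d sets control replicates 2 and 3 and periodontitis replicate 2 against the rest, with 674 genes higher and 879 lower in these 3. Of the 26 lists, 11 passed camera on this split, 10 lower and 1 higher, and 0 with an estimated correlation (lowest adjusted p = 0.407). The higher list was the mitochondrially encoded genes, which took 2.68% to 4.14% of counts in these 3 libraries and 1.73% to 2.20% in the others of that day, which also points to a structure of the samples other than the arms. With the real split counted among the 40, for the mean of days 3 of 40 drawn splits within days gave at least the real 873 calls (highest other 1046), for the interaction at 3 d 6 of 40 gave at least 3 (highest other 6) and at 7 d 5 of 40 at least 8 (highest other 1137), so that chance cannot be excluded for these 3 counts.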

How the results depend on the processing

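Settings that involve the neuron list or neuron-associated genes were chosen after seeing the data and the others before. Comparisons between arms are given by their day. Counts of genes that moved by more than 1.5 times were 2686 (0 d), 291 (3 d), 112 (7 d), 1601 (mean of days), 3064 (control 7 d vs 3 d), 2569 (periodontitis 7 d vs 3 d), 214 (interaction at 3 d) and 712 (interaction at 7 d) with DESeq2, 65 (0 d), 149 (3 d), 1075 (control 7 d vs 3 d) and 4724 (periodontitis 7 d vs 0 d) with only the groups compared, 133 (3 d), 40 (7 d), 27 (interaction at 3 d) and 110 (interaction at 7 d) without a low-count filter, 39 (3 d) with at least 1 CPM in 9 libraries, 4 (interaction at 7 d) with the muscle, erythroid, salivary and tooth lists removed, 992 (0 d), 0 (3 d) and 286 (mean of days) with the muscle covariate, 63 (0 d), 0 (3 d), 2 (7 d), 217 (mean of days), 243 (control 7 d vs 3 d), 612 (periodontitis 3 d vs 0 d), 2512 (periodontitis 7 d vs 0 d), 3 (periodontitis 7 d vs 3 d), 0 (interaction at 3 d) and 0 (interaction at 7 d) without the neuron-rich libraries, 190 (0 d), 44 (3 d), 4035 (periodontitis 7 d vs 0 d), 255 (periodontitis 7 d vs 3 d), 5 (interaction at 3 d) and 1 (interaction at 7 d) with the neuron covariate, 0 (0 d), 0 (3 d) and 10 (mean of days) with both covariates and 56 (3 d) with neuron-associated genes removed. Without the neuron-rich libraries 1 periodontitis library is left at 0 d and 1 at 3 d, so those counts also reflect fewer samples. The cause was not tested. RLE size factors and library totals moved no count by over 1.5 times.

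Leaving out each library in turn gave counts of 258 to 2121 (0 d), 0 to 13 (3 d), 0 to 1 (7 d), 458 to 1082 (mean of days), 5269 to 5544 (control 3 d vs 0 d), 6426 to 7503 (control 7 d vs 0 d), 414 to 3495 (control 7 d vs 3 d), 2520 to 3411 (periodontitis 3 d vs 0 d), 5485 to 6675 (periodontitis 7 d vs 0 d), 83 to 662 (periodontitis 7 d vs 3 d), 1 to 143 (interaction at 3 d) and 2 to 419 (interaction at 7 d). Lists called ranged over 11 to 14 (0 d), 15 to 17 (3 d), 10 to 17 (7 d), 11 to 16 (mean of days), 7 to 9 (control 3 d vs 0 d), 10 to 11 (control 7 d vs 0 d), 10 to 14 (control 7 d vs 3 d), 10 to 16 (periodontitis 3 d vs 0 d), 12 to 15 (periodontitis 7 d vs 0 d), 7 to 15 (periodontitis 7 d vs 3 d), 8 to 14 (interaction at 3 d) and 6 to 11 (interaction at 7 d). With an estimated correlation 0 lists were called in each of the 12 comparisons, and with fry 3 (0 d), 1 (3 d), 0 (7 d), 6 (mean of days), 3 (control 7 d vs 3 d), 4 (periodontitis 7 d vs 3 d), 0 (interaction at 3 d) and 0 (interaction at 7 d) where this moved the number by over 1.5 times. For the interaction at 7 d, 15 lists were called without the neuron-rich libraries and 13 with the neuron covariate. The correlations with the control time course lay between -0.47 and -0.048 at 0 d, 0.012 and 0.12 at 3 d, and -0.14 and 0.038 at 7 d without 1 library; the last turned to 0.067 with the neuron covariate and 0.044 without the neuron-rich libraries, and the cause was not tested. The Schwann cell list turned with the neuron covariate to -0.16 at 0 d, 0.046 for periodontitis 7 d vs 0 d and 0.15 for the interaction at 7 d, and Nos1 at 0 d to -0.24 with both covariates.

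Replicate numbers do not pair the libraries: in no comparison did all 3 same-numbered pairs have correlated deviations above 0.1 (lowest per comparison between -0.53 and 0.060), and in 1 of 9 comparisons, the arms at 0 d, every sample correlated best with its own number. With the replicate block the counts were 1572 (0 d), 53 (3 d), 2 (7 d), 883 (mean of days), 6340 (control 3 d vs 0 d), 7592 (control 7 d vs 0 d), 1918 (control 7 d vs 3 d), 3870 (periodontitis 3 d vs 0 d), 7087 (periodontitis 7 d vs 0 d), 724 (periodontitis 7 d vs 3 d), 4 (interaction at 3 d) and 8 (interaction at 7 d). Of the called gene results named, those lost were 75 of 149 without the neuron-rich libraries, 35 of 149 with the neuron covariate, 59 of 62 with both covariates, 21 of 62 with the muscle covariate, 35 of 120 with only the groups compared, 1 of 149 with RLE (Ctsk, periodontitis 7 d vs 0 d), 3 of 149 with library totals (Cdh19 at 0 d, Csf3r at 3 d and Nop16), 3 of 149 without a filter (the same Ctsk, Sp7 in control 7 d vs 3 d and Nop16) and 0 of 148 with DESeq2; 1 turned, Nos1. With 3 libraries per group, a simulated 1.5-fold change at 0 d was called in 16.4% of genes.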

Other observations

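In this part the lists were written after the data had been seen, and the test of clock phase was chosen after its result; the test of ribosome biogenesis was written before its value was computed. All 7 measured megakaryocyte genes fell in periodontitis over the mean of days (median -1.62), among them Itga2b (-1.62 ± 0.21, adjusted p = 1.00e-03), Gp9 and Gp1ba, parts of the receptor for von Willebrand factor (-2.41 ± 0.38, adjusted p = 0.00269 and -1.45 ± 0.30, adjusted p = 0.0132), and Pf4, platelet factor 4 (-0.72 ± 0.15, adjusted p = 0.0127).

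Genes of ribosome biogenesis were lower in periodontitis at 0 d: of a list of 20, which leaves out the interaction genes, 12 were lower and 0 higher (median -0.58), with Polr1b, a subunit of RNA polymerase I (-0.75 ± 0.11, adjusted p = 0.00299), Nop2, a nucleolar methyltransferase (-0.65 ± 0.10, adjusted p = 0.00431), and Fbl, or fibrillarin (-0.66 ± 0.14, adjusted p = 0.0156). At 3 d and 7 d 0 and 0 were lower (medians -0.12 and 0.18). The hypothesis that the interaction genes Heatr1, Nop16, Nat10 and Pus7 reflect ribosome biogenesis as a whole is consistent with a median interaction of 0.75 at 7 d over these other 20 genes, none of which passed alone.

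Clock genes moved in both arms between 3 d and 7 d. Arntl, Npas2 and Clock, the activators, had a median of 1.83 in control and 1.40 in periodontitis, and 9 repressor and output genes -1.10 and -0.87, of which 7 and 7 were lower. The gap between activators and repressors was 2.92 in control and 2.27 in periodontitis, against -0.25 and -0.079 between 0 d and 3 d. Collection at another time of day at 7 d may account for this; the labels give no clock times, and a change of the clock with healing stays open. Hlf was also lower in periodontitis over the mean of days (-0.80 ± 0.13, adjusted p = 0.00271).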
